A study of Mus musculus with 6 samples.

How the data were processed

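RNA was measured by sequencing in the soft palate of mouse embryos at stage E14.5, in 3 control libraries and 3 libraries from embryos without Dlx5. Per the labels' protocols, the posterior part of the palate was cut off, RNA was extracted with RNeasy columns, and libraries were made with an Illumina TruSeq mRNA kit, which selects polyadenylated RNA. The submitters' processing notes name STAR 2.4.1d, Partek and the mouse genome build mm10. The annotation, the counting settings and the use of strand are not given in the sources used here. Nothing in the labels says that the libraries came from separate embryos, so p-values measure the spread between these samples, which may in part be technical.

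The deposited table holds estimated counts, 1 value per gene and library, for 49492 gene rows. The file describes itself as normalized, but its columns were not brought to a common total: they sum to between 6891798 and 11922442. Of the values above 0.5, 64.5% were whole within 0.001, as an estimation that divides shared reads among genes gives. Reads of near-identical genes can therefore be split. A further 1 column of the table matched no labelled sample and was not used. Each of the other columns was assigned by the match of its name to a sample's labels. No row lacked a name.

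Estimated counts were rounded to whole numbers. Genes were kept where the mean over the 6 libraries was at least 1 on the counts-per-million scale (CPM), which left 16218 genes. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, knockout against control, without a block, and with Benjamini-Hochberg adjustment at 0.05. Levels are TMM-normalized CPM, given as mean ± SD of 3 libraries. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic, and confidence intervals are 95%. The design fixed before the data were examined assumed normalized values and named limma-trend on log2 values with a pseudocount of 1 CPM. It allowed the edgeR count test only for raw whole-number counts, which these estimated counts were not before rounding. After the values had been seen, the count test was nevertheless made the main test, and limma-trend (limma 3.58.1) became an alternative.

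Before the data were examined, 32 gene lists were written from textbook knowledge. The 30 lists with at least 4 kept members were tested with limma's camera on log2(CPM + 1), with a preset correlation of 0.01 between genes, and again with a correlation estimated for each list and with fry. List medians are on this scale, which understates the change of low genes. Members were also counted after adjustment over the list alone. The rule for naming genes, fixed at the same time, takes the Dlx family and Fgf10. It adds the 10 higher and 10 lower genes with the largest log2 fold changes among those past the threshold, with groups that do not overlap, a mean of at least 5 CPM and no predicted gene. Where fewer than 10 passed, the list was filled in order of p-value. Some genes this rule selects are not reported here. Up to 4 members with the smallest p-values may be named from each list.

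Alternatives planned beforehand were other pseudocounts, no filter and a filter of 5 CPM, median-of-ratios and quantile normalization, limma variance models, a threshold of 0.1, limma treat against a 1.2-fold change, a replicate block, DESeq2 1.42.0, and each library left out in turn. Alternatives added after seeing the data were limma-trend with the pseudocount of 1, moved there from the design, library totals without TMM, removal of 6 rows that collect ribosomal RNA reads, and removal of trends over gene length and GC content. Coordinates, lengths and GC content came from GENCODE M21 on GRCm38, the assembly also called mm10. Its names matched 15820 of the 16218 kept genes. A further 3 lists, for sensory ganglion neurons, mature brain and embryonic neural tube, were written after the fixed lists had been seen and before these genes were looked at.

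The test was tried on simulated counts for the same 16218 genes, with 200 genes changed in each of 5 simulations. It recovered 12.2% of genes changed by a log2 fold of 0.5, 69.0% at 1 and 97.9% at 2. The changed genes were drawn from those with a mean of at least 5 CPM. No library was simulated to stand apart from the others, as knockout replicate 3 did in the data. These shares therefore need not hold for the real comparison. Of the genes called, 9.09% were unchanged, above the nominal 5%, while 4.73% of unchanged genes had an unadjusted p under 0.05. The neuron list, given a log2 fold change of -0.7, was called in 5 of 5 simulations, with 3 calls of other lists in all. These simulated genes varied independently, so this says nothing about lists whose members vary together. Figures were drawn with matplotlib 3.10.9.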

Results

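Gene expression was compared between soft palates of control mouse embryos and of embryos lacking Dlx5, a homeobox transcription factor of the pharyngeal arches, at stage E14.5. The series concerns how cranial neural crest cells and muscle precursors interact while the soft palate forms. There were 3 libraries in each group. Control libraries held 9554906, 11922442 and 6891798 estimated counts, and knockout libraries 8741020, 10541150 and 11492409. Knockout replicate 3 stood apart from the other libraries. Its mean correlation with them was 0.959, against 0.970 to 0.976 for the others, and 6 rows that collect ribosomal RNA reads took 13.0% of its counts, against 18.8% to 29.0%.

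Dlx5 fell in the knockout to 1.25 ± 0.402 CPM from 19.3 ± 5.88 CPM in controls (SD, n = 3 each). The log2 fold change was -3.93 (SE 0.32; adjusted p = 0.0205, edgeR quasi-likelihood). Estimated counts were 242, 193 and 113 in the controls and 7, 15 and 17 in the knockouts, so all 6 libraries matched their labels. Dlx5 lies on chromosome 6 from 6877805 to 6882085, minus strand (GRCm38). It was the only gene of 16218 past the threshold, with 1 lower and 0 higher. Further genes lay close behind: the second smallest adjusted p from edgeR was 0.0527, and 299 genes (42 higher, 257 lower) were under 0.1. At an unadjusted p under 0.05 there were 2081 genes (909 higher, 1172 lower), where 810.9 would be expected by chance. Groups did not overlap for 19.2% of genes, against 10% by chance.

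The number of genes called depended on the method. The limma-trend test named in the initial design, run as an alternative, called 97 genes (9 higher, 88 lower), quantile normalization with limma-trend 88 (9 higher, 79 lower), and DESeq2 501 (118 higher, 383 lower). Without knockout replicate 3, edgeR called 164 genes (12 higher, 152 lower), and without control replicate 3, knockout replicate 1 or knockout replicate 2 it called 0. Dlx5 itself then had an edgeR adjusted p of 0.107, 0.0949 and 0.0631, within a range of 1.78e-22 to 0.107 over 22 alternatives.

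The other Dlx genes were not lower in the knockout. Dlx6, the neighbour of Dlx5 in the genome, measured 8.94 ± 4.82 CPM in controls and 14.97 ± 2.20 CPM in knockouts (log2 fold change 0.74, SE 0.33; adjusted p = 0.407, edgeR). Without control replicate 1 its log2 fold change was 1.27 (adjusted p = 0.0987, edgeR) and without control replicate 3 it was 0.51 (0.697), the ends of the range over libraries left out. Estimates for Dlx1 (0.44), Dlx2 (0.36), Dlx3 (0.36) and Dlx6os1 (0.58) were also above 0 under every alternative that gave a value, and none passed the main test; the filter of 5 CPM removed Dlx6os1. Dlx6 overlaps Dlx6os1 on the opposite strand over 5235 bases, and with the use of strand not given it is not known whether reads of this pair were told apart. Dlx4 had 9 counts in all controls and 36 in all knockouts, and Dlx1as had 16 and 26, both under the filter. As a list the Dlx family was not called (adjusted p = 0.581, camera), with a median of 0.38 and, because of Dlx5, a mean of -0.14. The median ran from 0.17 to 0.50 over libraries left out.

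Fgf10, which encodes a growth factor of mesenchyme, measured 9.49 ± 0.809 CPM in controls and 14.97 ± 3.18 CPM in knockouts. Every knockout library lay above every control library. The log2 fold change of 0.66 (SE 0.19; 95% confidence interval 0.22 to 1.10) did not pass the test (adjusted p = 0.186, edgeR). Among 17 FGF ligands and receptors and 11 FGF response genes, 0 passed when adjusted over the list alone. However, 1 higher and 2 lower FGF ligands and receptors did so without knockout replicate 3, and 1 lower without knockout replicate 1.

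**Figure D1:**
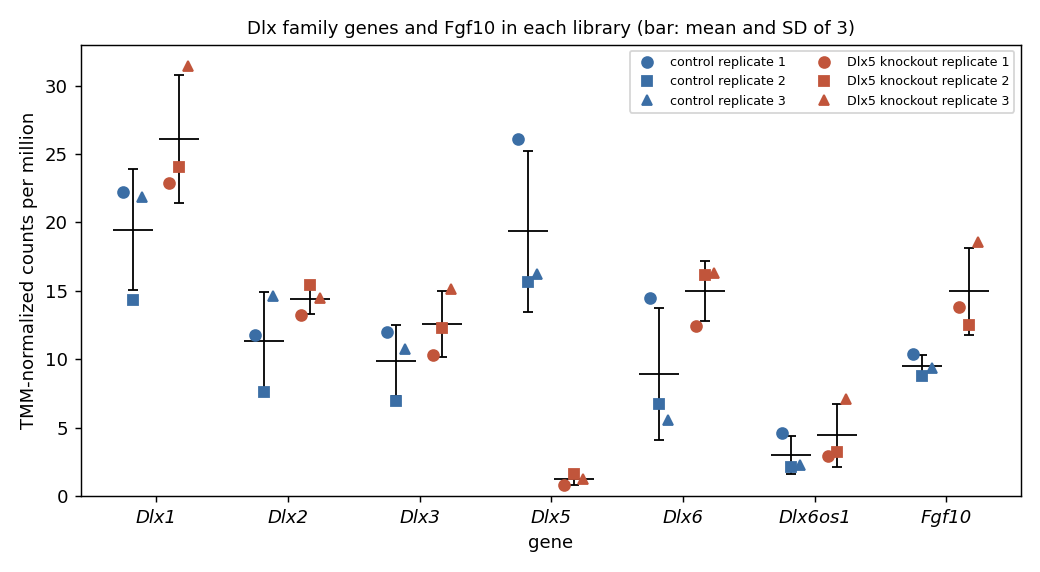
TMM-normalized CPM (vertical axis) of Dlx family genes and Fgf10 in each library, with controls in blue and knockouts in red; black bars give the mean and SD of 3 libraries. Dlx5 averages 19.3 in controls and 1.25 in knockouts, and it alone passes the test.

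The named genes with higher estimates were Tmem26, Cdon, Tmod1, Lmx1a, Mab21l2, Ube2c, Tex15, Aldh1a3, Irx1 and Snx1. None passed, with edgeR adjusted p from 0.0527 to 0.0710. Cdon, a cell surface receptor that promotes muscle differentiation and binds Hedgehog ligands, measured 51.4 ± 5.98 CPM in controls and 94.6 ± 10.6 CPM in knockouts. Irx1 had a log2 fold change of 1.85, Lmx1a of 1.64, Tmod1 (an actin-capping protein) of 1.41 and Aldh1a3 (an enzyme of retinoic acid synthesis) of 1.29. After Dlx5, the named genes with lower estimates included Pgm2l1, Map7, Sv2c, Gnao1, Sarm1, Kcna2, Myt1l and Pla2g7. None of these passed, each with an edgeR adjusted p of 0.0527. Several act in neurons: Sv2c of synaptic vesicles had a log2 fold change of -1.12, the neuronal transcription factor Myt1l of -0.92 and the axonal potassium channel Kcna2 of -0.81.

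**Figure D2:**
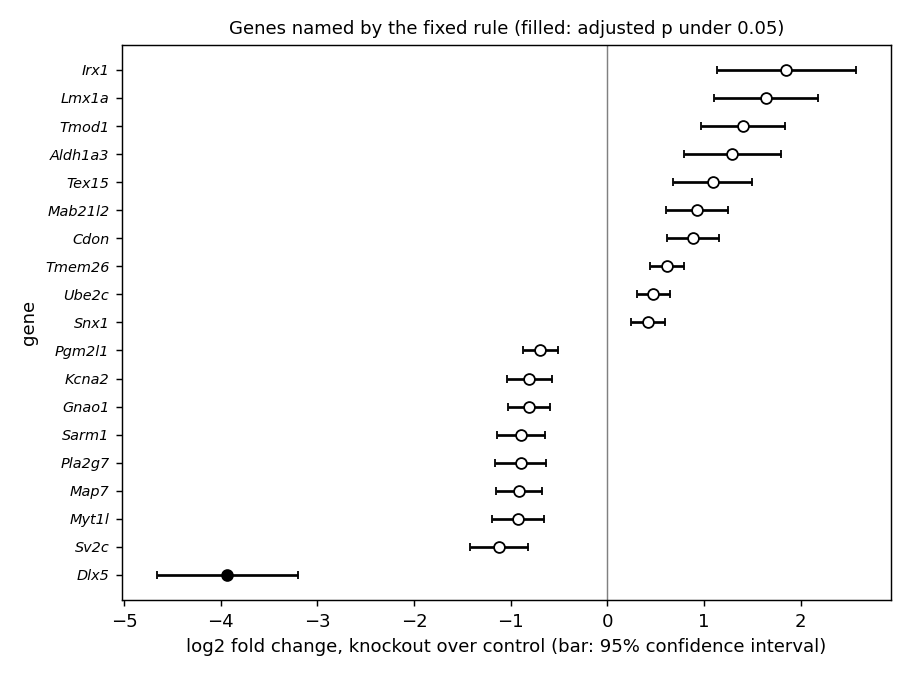
Log2 fold changes, knockout over control (horizontal axis), of Dlx5 and the higher and lower genes named here by the fixed rule, with 95% confidence intervals. The other Dlx genes and Fgf10 are not drawn. Filled points have an adjusted p under 0.05 (edgeR). Dlx5, at -3.93, is the only filled point.

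Of 30 gene lists tested with camera, 11 passed at a preset correlation of 0.01, with 5 higher and 6 lower in the knockout. With an estimated correlation 0 lists passed, and with fry 0. Apart from Dlx5, no member of any list passed when adjusted over all genes with all libraries. Without knockout replicate 3, 10 of 20 neuron genes passed on that basis, all lower, and no other list had more than 1 such member. Without control replicate 3, knockout replicate 1 or knockout replicate 2, no gene passed at all.

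Neuron genes were lower in the knockout, with a median log2 fold change of -0.74 over 20 genes (adjusted p = 5.76e-17, camera at the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.377, camera). Adjusted over the list alone, 16 were lower, 0 higher and 4 did not pass, and with 1 library left out 16 to 18 were lower. The neurofilament gene Nefm measured 1274 ± 222 CPM in controls and 649 ± 114 CPM in knockouts, and the neuronal tubulin gene Tubb3 342 ± 36.5 and 197 ± 35.4 CPM. The log2 fold change was -0.79 for Elavl3, a neuronal RNA-binding protein, and -0.82 for Chga, a protein of secretory granules. List medians in knockout replicates 1, 2 and 3, relative to controls, were -0.57, -0.84 and -0.87. Knockout replicate 3 at the same time held brain transcripts, among them the astrocyte gene Gfap, chosen after its values were seen, at 40.4 CPM against at most 2.37 in the other libraries.

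Pituitary and brain genes were lower as a list (median -0.76 over 15 genes; adjusted p = 0.00138, camera at the preset correlation), a call lost with an estimated correlation (adjusted p = 0.377, camera). There were 6 lower and 1 higher genes when adjusted over the list alone, and 2 to 8 lower and 0 to 3 higher with 1 library left out. Six3, a homeobox gene of the anterior head, measured 14.8 ± 5.24 CPM in controls and 2.75 ± 1.62 CPM in knockouts. Cga, the shared subunit of pituitary hormones, measured 10.3 ± 2.32 and 3.48 ± 1.07 CPM. Of the 15 estimates, 10 were lower and 5 higher. Some brain members, chosen after their values were seen, rose in knockout replicate 3. Gad1 measured 52.7 CPM there against at most 2.49 in the other libraries, Gad2 22.3 against 1.62, and Tbr1 6.79 against 1.15. The mature brain list, written later, had a median edgeR log2 fold change of 0.75 over 30 genes. Schwann cell and glia genes were not called (median -0.01 over 14 genes; adjusted p = 0.857, camera).

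Skeletal muscle genes were higher in the knockout, with a median log2 fold change of 0.86 over 44 genes of the contractile apparatus (adjusted p = 1.52e-15, camera at the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.740, camera). Of these genes, 14 were higher, 0 lower and 30 did not pass when adjusted over the list alone. With 1 library left out this count of higher genes ran from 0 to 36: 0 without control replicate 1 or 3, 1 without knockout replicate 2, 24 without knockout replicate 3 and 36 without knockout replicate 1. Myl1, a myosin light chain, measured 46.5 ± 6.48 CPM in controls and 99.7 ± 31.0 CPM in knockouts, and Tnnt2, a troponin, 21.9 ± 5.01 and 52.0 ± 19.7 CPM. The spread lay between knockout libraries: list medians relative to controls were 0.12, 1.47 and 0.82 in knockout replicates 1, 2 and 3, and -0.06, 0.34 and -0.28 in the controls. Without knockout replicate 2 the median was 0.47.

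Myogenic progenitor genes were higher as a list (median 0.57 over 26 genes; adjusted p = 4.17e-05, camera at the preset correlation), a call lost with an estimated correlation (adjusted p = 0.608, camera). In this list 8 were higher and 1 lower, adjusted over the list alone, against 1 to 12 higher and 0 to 1 lower with 1 library left out (3 and 0 without knockout replicate 3). Myod1, a master regulator of skeletal muscle, measured 12.2 ± 2.32 CPM in controls and 21.1 ± 5.29 CPM in knockouts. Chrna1, a subunit of the muscle acetylcholine receptor, measured 5.06 ± 2.35 and 13.3 ± 2.22 CPM.

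Cell cycle genes were higher, with estimates above 0 for all 28 (median 0.25; adjusted p = 1.82e-11, camera at the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.377, camera). When adjusted over the list alone, 11 were higher, but 0 to 7 with 1 library left out and 1 without knockout replicate 3. Birc5, which acts in cell division, measured 34.0 ± 1.41 CPM in controls and 45.6 ± 3.66 CPM in knockouts. Hedgehog pathway genes were higher as a list (median 0.16 over 14 genes; adjusted p = 0.0383, camera at the preset correlation), with an adjusted p = 0.608 (camera) with an estimated correlation. Adjusted over the list alone, 3 were higher and 0 lower (2 to 4 higher and 0 to 2 lower with 1 library left out). Among the higher was Gas1, a co-receptor, at 61.0 ± 10.1 CPM in controls and 103 ± 14.2 CPM in knockouts. This call ended without control replicate 2 (adjusted p = 0.111, camera), knockout replicate 2 (0.165) or knockout replicate 3 (0.0567), in a range of 0.0157 to 0.165 over libraries left out. It also ended with library totals in place of TMM (median 0.14; adjusted p = 0.0784, camera) and with a replicate block (0.0593).

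Hox genes and their cofactors, which pattern the hindbrain and posterior arches, were higher as a list (median 1.17 over 6 genes; adjusted p = 5.78e-05, camera at the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.608, camera). Of the 6, 5 were higher when adjusted over the list alone, as with any 1 library left out. The filter, set on all 6 libraries and reused in those fits, kept 6 of 18 written members. Hoxa3 and Hoxb3 passed it only through knockout replicate 3, so these counts are no independent support, even without that library. Hoxd3, with 34 counts in all controls and 19 in all knockouts, was removed. Hoxa2 had 15, 21 and 5 counts in controls and 47, 46 and 242 in knockouts. Hoxb3 had 1, 0 and 0 counts in controls and 9, 4 and 65 in knockouts. The cofactor Meis1 measured 23.3 ± 4.82 CPM in controls and 53.2 ± 19.6 CPM in knockouts. List medians were 0.68, 0.64 and 2.10 in knockout replicates 1, 2 and 3, so knockout replicate 3 was the highest. Without it the list median was 0.63, the low end of a range of 0.63 to 1.38 over libraries left out, and over all alternatives it ran from 0.25 to 1.79.

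Osteoblast genes were lower as a list (median -0.63 over 15 genes; adjusted p = 0.00145, camera at the preset correlation), with an adjusted p = 0.786 (camera) with an estimated correlation. Of them 0 passed when adjusted over the list alone, and 0 to 8 were lower with 1 library left out. Alpl, a phosphatase of mineralizing bone, measured 61.1 ± 11.3 CPM in controls and 33.1 ± 24.5 CPM in knockouts. List medians were -0.58, 0.13 and -1.40 in knockout replicates 1, 2 and 3, and without knockout replicate 3 the median was -0.21 (adjusted p = 0.147, camera; 1.46e-08 to 0.147 over libraries left out).

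Oral epithelium genes were lower as a list (median -0.19 over 27 genes; adjusted p = 0.00661, camera at the preset correlation), with an adjusted p = 0.786 (camera) with an estimated correlation. Among them 5 were lower when adjusted over the list alone (0 to 8 with 1 library left out), for example the keratin Krt17 (53.5 ± 23.4 CPM in controls, 15.7 ± 6.53 CPM in knockouts). Without control replicate 3 the median was -0.00486 and the adjusted p = 0.337 (camera), and without knockout replicate 2 the adjusted p was 0.0543, in a range of 0.000197 to 0.337. Hypoxia and glycolysis genes were lower as a list (median -0.24 over 22 genes; adjusted p = 0.00338, camera at the preset correlation), with an adjusted p = 0.786 (camera) with an estimated correlation. Adjusted over the list alone, 2 were lower (1 to 3 with 1 library left out), among them the glycolytic enzyme Pfkp (53.3 ± 4.29 and 29.6 ± 5.56 CPM). Without control replicate 3 the median was -0.04 (adjusted p = 0.717, camera; 5.01e-05 to 0.717 over libraries left out). Endothelium genes had a median of -0.12 over 16 genes (adjusted p = 0.0383, camera at the preset correlation; adjusted p = 0.786 with an estimated correlation), with 0 passing when adjusted over the list alone (0 to 1 lower with 1 library left out). That call ended without control replicate 3 (adjusted p = 0.201, camera) or knockout replicate 3 (0.291), in a range of 0.0131 to 0.291 over libraries left out, and with a filter of 5 CPM (median -0.12; adjusted p = 0.0664, camera). The endothelium median was -0.06 without knockout replicate 3, in a range of -0.18 to -0.06 over libraries left out.

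**Figure D3:**
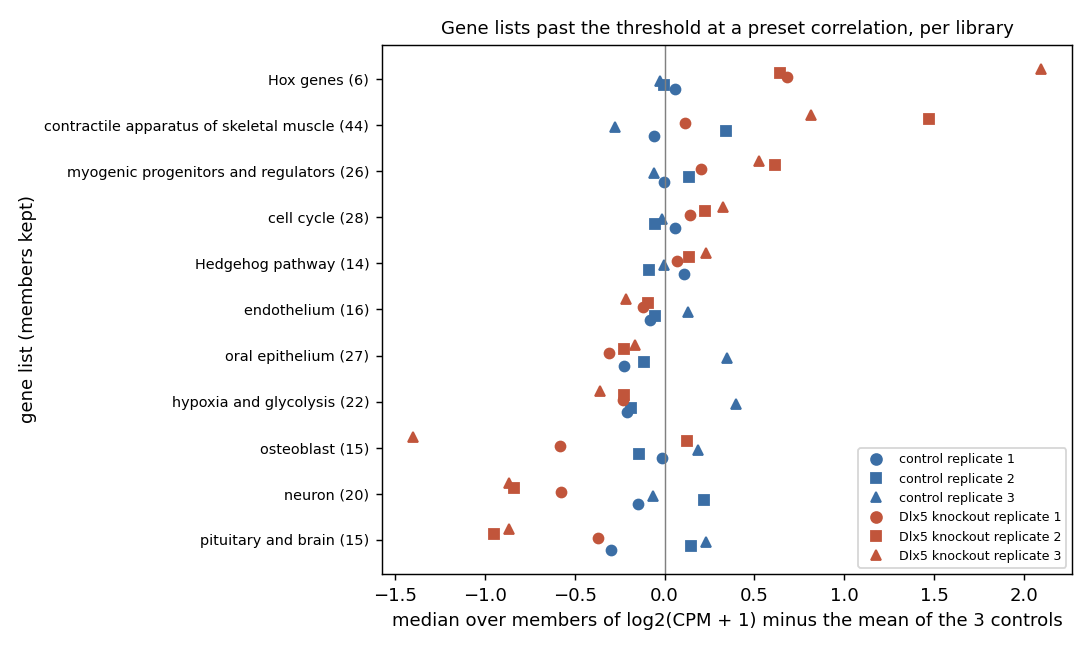
Median over list members of log2(CPM + 1) minus the mean of the controls (horizontal axis), per library, for the 11 lists past the threshold at the preset correlation; controls are blue, knockouts red, and shapes mark replicates. In the contractile list knockout replicates 1, 2 and 3 lie at 0.12, 1.47 and 0.82.

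The remaining 19 tested lists were not called. Palatal mesenchyme regulators had a median of -0.12 over 20 genes (adjusted p = 0.581, camera). Adjusted over the list alone, 2 were higher (0 to 2 with 1 library left out) and 3 lower (0 to 4), the latter being Lhx8 (log2 fold change -1.19), Pax9 (-0.67) and Tbx3 (-0.65), transcription factors of the palate and teeth. Chondrocyte genes had a median of 0.28 over 20 genes (adjusted p = 0.201, camera), which passed without knockout replicate 3 (median 0.80; adjusted p = 5.48e-10) and without control replicate 1 (0.52; 0.00101), in a range of 5.48e-10 to 0.886 over libraries left out, and with library totals in place of TMM (0.26; adjusted p = 0.0243, camera). Over libraries left out the chondrocyte median ran from -0.03 to 0.80, so its direction was not stable. Adjusted over the list alone, 0 members passed (0 to 6 higher with 1 library left out). Sox9, the master regulator of chondrocytes, measured 185 ± 73.4 CPM in controls and 319.5 ± 47.5 CPM in knockouts (adjusted p = 0.237, edgeR). Pharyngeal arch genes had a median of -0.03 over 29 genes (adjusted p = 0.699, camera). Wnt pathway genes had a median of 0.10 over 34 genes (adjusted p = 0.1996, camera), with 1 higher when adjusted over the list alone (0 to 2 with 1 library left out), the Wnt antagonist Nkd1. That list passed without control replicate 3 (median 0.21; adjusted p = 0.0305, camera; 0.0305 to 0.429 over libraries left out). The erythroid list held 1 lower gene, Sptb, and the macrophage list 1 lower gene, Coro1a, each adjusted over the list alone; without control replicate 3 the erythroid count was 0, while the macrophage count stayed at 1 with any library left out. The retinoic acid list held 1 higher gene, Aldh1a3, and 1 lower on the same basis (1 to 2 higher and 0 to 4 lower with 1 library left out). The glia list held 0 higher and 1 lower (0 to 2 higher and 0 to 2 lower). The median, mean and camera direction differed in sign for the Dlx, pharyngeal arch, tendon, macrophage, glia, salivary, BMP and immediate early lists, all uncalled. All 37 mitochondrially encoded rows were listed at 0 in every library, so that list was not tested.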

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

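Tests with library totals, without ribosomal rows and with length and GC trends removed were chosen after seeing the data, and limma-trend at a pseudocount of 1, named in the initial design, was made an alternative then. Against 1 gene past the threshold in the main test (0 higher, 1 lower), limma-trend called 97 (9 higher, 88 lower) with a pseudocount of 1 CPM, 94 (9 and 85) with 0.25 and 93 (8 and 85) with 4. Quantile normalization gave 88 (9 and 79), limma-trend with robust variances 149 (14 and 135), and limma without the variance trend 0. Without a filter on low values edgeR called 679 (244 higher, 435 lower), and with a filter of 5 CPM 74 (6 and 68). Library totals without TMM gave 41 (0 and 41), DESeq2 501 (118 and 383), and an adjusted p under 0.1 gave 299 (42 and 257). Leaving out 1 library at a time gave 0 to 164 genes, 0 to 12 of them higher and 0 to 152 lower. The count was 6 without control replicate 1, 4 without control replicate 2, and 164 without knockout replicate 3. Of those 164, 125 were among the 299 under 0.1 with all libraries. Median-of-ratios factors, limma treat, removal of ribosomal rows and removal of length and GC trends each gave 1 gene. What made the counts differ was not tested.

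No label says what the replicate numbers mean. Deviations of same-numbered libraries correlated at -0.01, -0.01 and 0.02, which shows no shared deviation but does not exclude a shared litter or day. With a replicate block, 0 genes were called, 0 of them lower, and Dlx5 had a log2 fold change of -3.88 (adjusted p = 0.0620, edgeR). The block leaves fewer degrees of freedom. Dlx5 was lower under all 22 alternatives (-4.15 to -2.13; adjusted p from 1.78e-22 to 0.107). It missed the threshold with limma without the variance trend (-3.16; adjusted p = 0.0928), with the block, and in 3 of the 6 fits that left out a library (range -4.15 to -3.65). Fgf10 stayed above 0 (0.47 to 0.77) and did not pass 0.05 in any of them.

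Of the gene lists past the threshold, 11 at the preset correlation, 0 remained with an estimated correlation and 0 with fry. With fry, the neuron, cell cycle and pituitary lists each had an adjusted p of 0.0994. Leaving out 1 library gave 9 to 12 lists. The replicate block ended the Hedgehog call (adjusted p = 0.0593) and no other list call. The tendon list, uncalled with all libraries (median 0.07), turned to -0.26 without knockout replicate 2 (adjusted p = 0.0398; range over libraries left out -0.26 to 0.13), and the cause was not tested. Among 3036 values of 139 named genes under the alternatives, 18 differed in sign from the main value, none of a called gene. Named genes under the filter of 5 CPM, such as Dlx6os1, had no value there. Depth limits what can be read of genes such as Dlx4, Dlx1as and most Hox genes, which had few counts.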

Other observations

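The tests of library scaling, of glia genes, of knockout replicate 2 and of other splits were chosen after the results they bear on had been seen. Some genes outside the naming rule stood out, chosen after their values were seen. Ttr, a transport protein made by the choroid plexus, measured 629 CPM in knockout replicate 1 and 19.0 CPM in knockout replicate 3, against at most 1.29 CPM in the other libraries. Hoxa3 had 0 counts in all controls and 2, 7 and 64 in the knockouts, and Hoxb5 had 0 in all controls and 2, 4 and 49 in the knockouts. The ribosomal RNA row AY036118 had 337 counts in knockout replicate 3 and 69500 to 142223 elsewhere.

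Neuron genes were lower in the knockout at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.377, camera) and with fry (0.0994). Under 3 other scalings of the libraries the median nearest to 0 was -0.74. These scalings hardly moved the median edgeR log2 fold change over all genes (0.0031 to 0.0144, against 0.0139 in the main test). They therefore could not decide whether a larger error of scaling played a part. Gene length and GC content are argued against as the whole cause. The median was -0.74 after both trends were removed, where the control library medians had an SD of 0.19. A candidate explanation is that the knockout pieces held fewer sensory ganglion neurons: the median over 23 genes of that list was -0.94, with 20 lower and 0 higher at an unadjusted p under 0.05, and 22 of them reach 5 CPM in a library other than knockout replicate 3. An equal fall of all nervous tissue is argued against for the listed genes, mainly by knockout replicates 1 and 2. Glia medians in knockout replicates 1, 2 and 3 were -0.06, -0.28 and 0.09, where neuron medians were -0.57, -0.84 and -0.87. Control glia medians ran from -0.20 to 0.11. The brain transcripts in knockout replicate 3 limit its glia value. Whether glia genes fell by a smaller amount or not at all stays open, as their median was -0.0147 with all libraries and -0.20 without knockout replicate 3. A smaller ganglion in the embryo and a different line of dissection would give the same values, and neither was tested.

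Skeletal muscle genes were higher in the knockout at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.740, camera) and with fry (0.477). The lowest median under 3 other scalings was 0.84, but these scalings hardly moved the median gene, so they could not decide on a larger error of scaling. The list median was 0.85 after length and GC trends were removed, where the control library medians had an SD of 0.31. This argues against gene length and GC content as the whole cause. Whether knockout replicate 2 alone carries the difference stays open: without it the median was 0.47, above 0.4 by less than that SD, and knockout replicate 1, at 0.12, lay within the range of the controls. Against it, knockout replicate 3 lay above every control at 0.82, and the call without knockout replicate 2 was kept at the preset correlation (adjusted p = 1.46e-08, camera; 2.12e-32 to 1.46e-08 over libraries left out), but this rests on 1 library. More muscle tissue in some knockout pieces may account for this and was not tested.

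Knockout replicate 3 held brain transcripts. In it 156 of 16218 genes exceeded 3 times the highest other library, against 1 to 15 genes in each of the others, among them, chosen after their values were seen, Camk2a at 150 CPM, Slc1a2 at 150 CPM, Mbp at 177 CPM and Mobp at 66.8 CPM. Embryonic neural tissue is argued against, as 0 of 21 genes of the neural tube list did so (0%), among them 0 of the 9 that stay under 5 CPM in every other library. The other 12 could hide a small share, and Hoxa2, Hoxb3 and Hoxa3, which also mark hindbrain, are among the 156. RNA of mature brain in this library may be a source. Of that list, 13 of 30 genes exceeded 3 times the highest other library (43.3%). Of the 26 that reach a mean of 1 CPM in the other libraries, 9 did so (34.6%). Both shares lie between the bounds of 20 and 50% set beforehand. All 6 members that stay under 5 CPM in every other library did so, but some of them passed the filter only through knockout replicate 3. The other 24 of the 30 reach 5 CPM in another library, which can hide a small share.

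The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1 gene past the threshold and the highest other split 4, and 4 of the 10 splits gave at least 1. For gene lists at the preset correlation the real split gave 11 and the highest other split 13, and 4 of the 10 splits gave at least 11.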
